A study of Homo sapiens with 6 samples.

How the data were processed

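Total RNA of HT1080 cells was measured on Illumina HumanRef-8 bead arrays. HT1080 is a human fibrosarcoma line, and on these arrays each probe is carried by many beads whose brightness is averaged. Per the labels' protocols, biotin-labelled cRNA was stained with streptavidin-Cy3. The 6 arrays analysed fall into 3 groups of 2 biological replicates: parental cells (HT), a pool stably transfected to produce wild type membrane type-1 matrix metalloproteinase (MT1-MMP, gene symbol MMP14), called HT-MT, and cells stably carrying an siRNA construct against MT1-MMP (HT-siRNA). The vector and scrambled siRNA controls that the series' design describes were not analysed here. The labels name the replicates as biological, but each transfected group is described as a single pool of cells. The p-values therefore measure at most the spread between cultures of a pool and not the spread between independent transfections. If the replicates were repeated labellings of the same RNA, they would measure technical spread only. The label of HT replicate 1 names no transfected pool, and this array was taken as parental from its cell source. In HT-MT replicate 2 the title and the description disagree, and the title was followed.

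The main values were the signal intensities of the deposited normalized table, which the authors normalized between arrays by a method that is not given in the sources used here. BeadStudio is named in the submitters' processing notes without a version. The signals ranged from 58.7 to 61340 on a linear scale, so they were not background-subtracted to 0, and the array medians lay between 189.2 and 189.3. The detection p-value of each probe on each array was also deposited, per the file headers, as were the number of beads and the standard error over beads. An array of the same chip that matched no sample label had 4 columns of values, which were not used. A second deposited table held linear signal intensities of the same 6 arrays. Its array medians ran from 164.6 to 209.8, each of its columns correlated with the normalized column of the same sample at r of 0.9985 to 0.9999 on the log2 scale, and 1 of its values was empty. Its scale and any centring by the authors are not stated, and it served as an alternative only.

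The table held 24365 probe entries, of which 8 were controls without a gene symbol. Gene symbols were those of the array design, brought up to date with a RefSeq gene table (assembly GRCh38.p14) that was used for names only, with no coordinates. Of the 24357 probes with a symbol, 12457 had a current symbol, 4297 an older one that could be updated, 347 an ambiguous one and 7256 one that matched nothing and was kept as given. Signals were floored at 16 and put on the log2 scale; no signal was at the floor. A probe was kept when its detection p was under 0.01 on both arrays of at least 1 group, which left 6540 probes. For each symbol the kept probe with the highest mean over the 6 arrays was used, which left 6336 genes. Of these genes 187 had several kept probes. Probes of the same gene were past the threshold in opposite directions for 3 genes in HT-MT against HT, 11 in HT-siRNA against HT and 1 in HT-MT against HT-siRNA, none of them among the genes named here. Probes of gene families with near-identical members, for example the MAGE and VCX genes, the HLA genes, HSPA1A with HSPA1B, and F8A1, can bind transcripts of several members, so their values are uncertain as to the member.

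Some names were updated from those of the file, in which CADM1 is IGSF4, VCAN is CSPG2, PDPN is T1A-2, SMAD3 is MADH3, PXDN is D2S448 and CCN2 is CTGF.

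Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 3 group means and eBayes; 3 residual and 6.739 prior degrees of freedom). The p-values were two-sided and adjusted by the Benjamini-Hochberg method over the 6336 genes, with a threshold of 0.05. A permutation of 2 against 2 arrays cannot give a p under 0.3333, so no permutation test was used. A gene whose probes were detected on no array of a group has only a bound in that group. Its change is given as "at least" a fold: the mean of the brighter group against the mean, over the arrays of the dim group, of the lowest detected signal of the array or the probe's own signal, whichever was higher, with means on the log2 scale. No fold is given where both groups were below detection or where that bound was under 1. Other folds are fitted values on the floored log2 scale.

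The genes named were chosen by a rule written before the data were examined. It took MMP14 always; per comparison the 10 genes that rose and the 10 that fell most, among those with an adjusted p under 0.05 and both arrays of a group above both of the other; up to 4 members with the largest changes of each list; up to 10 genes each for the opposite-direction and the ordered genes; and every member of a list of another cell type that passed the threshold. In all 333 named calls both arrays of a group lay above both arrays of the other (n = 2 in each group).

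A set of 25 gene lists was fixed with that rule. They were matrix metalloproteinases other than MMP14, other pericellular proteases and inhibitors, extracellular matrix, integrins and focal adhesion, TGF-beta and BMP signalling, Wnt and Dickkopf signalling, angiogenic factors, hypoxia response and glycolysis, cell cycle and mitosis, p53 targets, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, unfolded protein response and amino acid stress, cholesterol synthesis, endocytosis and membrane trafficking, Notch signalling, mesenchymal markers, cytosolic ribosomal proteins, oxidative phosphorylation, heat shock and chaperones, and markers of epithelial, glial, leukocyte and endothelial cells, and 1 list that is not reported here. The 20 lists with at least 5 genes tested were tested with limma's camera at its preset correlation of 0.01, adjusted over the 20 lists of each comparison. Camera with an estimated correlation and fry were run as alternatives. Fry asks whether a list's genes move, on balance, in a single direction, and does not compare them with other genes. The median, mean and test of a list differed in sign in 8 of 60 list tests, none of them called. They were integrins, Wnt and Dickkopf signalling and mesenchymal markers in HT-MT against HT. In HT-siRNA against HT they were Wnt and Dickkopf signalling and mesenchymal markers, and in HT-MT against HT-siRNA Wnt and Dickkopf signalling, angiogenic factors and Notch signalling.

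The comparisons of both transfected pools with HT share the HT arrays. Their overlap was set beside 100 simulations of unchanged groups against shared controls and beside the overlap of independent lists. On simulated data for HT-MT against HT with 6336 genes, of which 33 or 34 were changed per direction and size, the fit recovered 100% of the genes changed by 1.5-, 2- and 4-fold and called 17 unchanged genes. The noise was independent and drawn from the fit's own spread, and far fewer genes were changed than passed on the real arrays. The simulation therefore checks the fitting steps and does not measure power on these arrays.

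Alternatives tried were floors of 8 and 32, an added offset of 50, median centring, quantile normalization, no filter on dim probes, probes detected on all 6 arrays, every probe on its own, an intensity trend in eBayes, only the 4 arrays compared, the replicate number as a block, the second table's values, and leaving out each array in turn. Some settings repeat a fit. Floors of 8 and 32 changed no value, since the lowest signal was 58.7. Median centring changed little, since the array medians were nearly equal. Leaving out an array of the group outside a comparison gives the fit of only the 4 arrays compared. Counts of settings include these repeats. A detection threshold of 0.05 and the second table after median centring or quantile normalization were added after seeing the data, as were replicate blocks on the HT and HT-MT arrays alone with the HT-MT numbers as given and crossed, which were run for the count of genes only. The limma fit to the second table as deposited gave MMP14 an adjusted p of 6.48e-303 between HT-MT and HT-siRNA, against 1.81e-08 in the main fit. A p so small from 2 against 2 arrays implies a spread nearly common to all genes. Its p-values and calls are therefore not comparable with the main ones. All 6 arrays sat on the same chip, so chip could not be a block, and the replicate block also parts the chip's earlier from its later positions. The precision is limited by the 2 arrays per group. Between 5795 and 6614 probes per array were detected (23.8% to 27.2%), the lowest detected signal of an array was between 436.1 and 515.2, and the median number of beads per probe was 31. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.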

Results

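The series compared gene expression in HT1080 fibrosarcoma cells (HT), which make the membrane-anchored collagenase MT1-MMP naturally, with a pool transfected to make more of it (HT-MT) and with cells in which it was to be silenced (HT-siRNA). Each group had 2 arrays, and 6336 genes were tested. Replicates resembled each other more than they resembled any array of another group: over all probes, r on the log2 scale was 0.9927 between the HT arrays, 0.9962 between the HT-MT arrays and 0.9950 between the HT-siRNA arrays, and at most 0.9825 between groups. No gene tested differed by 2-fold or more between replicates. Between replicates 48.9%, 24.1% and 28.4% of genes in HT, HT-MT and HT-siRNA differed by over 2 standard errors of the bead means. That does not tell separate cultures from repeated labellings of the same RNA. The first principal component held 58% of the variance and set HT against HT-siRNA with HT-MT between them, and the second held 34.6% and set HT-MT against both others.

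MMP14, the gene of MT1-MMP, gave signals of 6470 and 8654 on the HT arrays, 6254 and 5896 on the arrays labelled HT-MT, and 190 and 220 on the HT-siRNA arrays. In HT-siRNA the probe was detected on neither array, and MMP14 was at least 15.7-fold lower than in HT (adjusted p = 5.45e-09). On the arrays labelled HT-MT it was not higher than in HT: the difference was -0.30 ± 0.13 (SE) on the log2 scale, toward a lower signal, and did not pass the threshold (adjusted p = 0.0977, unadjusted p = 0.0470). That difference passed it without HT replicate 1 (-0.51, adjusted p = 0.0095), with the replicate number as a block (adjusted p = 0.0413) and from the second table after median centring (-0.46, adjusted p = 0.0118). It shrank to -0.0914 without HT replicate 2 (adjusted p = 0.5303), and the adjusted p lay between 0.0095 and 0.5303 over 20 settings, of which 17 did not pass. The 17 are not separate checks. Both other floors on the signal returned the main values, and median centring of the main table hardly changed the difference (-0.3009). Leaving out either HT-siRNA array repeated the fit of only the HT and HT-MT arrays. Median centring of the second table also moved the median difference of all genes tested to -0.12, against -0.0023 in the main fit. As deposited, that table gave an MMP14 difference of -0.26 (adjusted p = 0.1264, not comparable with the main fit), and after quantile normalization -0.32 (adjusted p = 0.0899). MMP14 was at least 12.7-fold higher on the arrays labelled HT-MT than on those of HT-siRNA (adjusted p = 1.81e-08). The position of the MMP14 probe relative to the transfected sequence is not known here, so its signal cannot check the label HT-MT. Directions given for these arrays rest on the label.

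**Figure D1:**
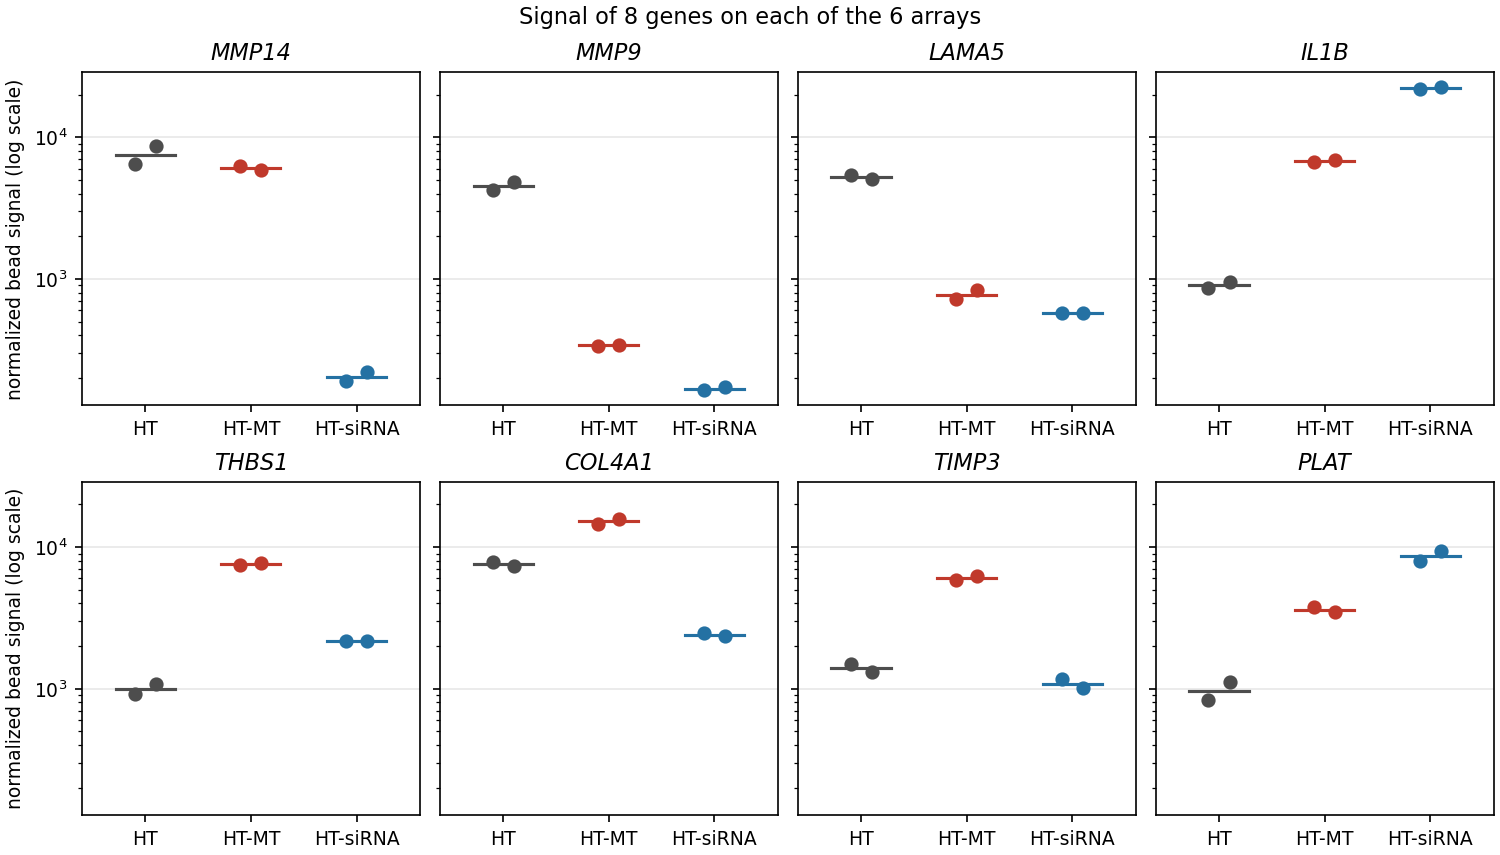
Normalized bead signal (log scale) of MMP14, MMP9, LAMA5, IL1B, THBS1, COL4A1, TIMP3 and PLAT on each of the 6 arrays; each point is an array and each line a group mean of 2 arrays. MMP14 lies at 190 and 220 on the HT-siRNA arrays and at 5896 to 8654 on the other 4, and MMP9 and LAMA5 lie lower than HT on all 4 arrays of the transfected cells.

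The comparison of HT-MT with HT was designed to ask what raised MT1-MMP changes, though the MMP14 signal was not higher on the arrays labelled HT-MT. By fitted values SULF2, an extracellular sulfatase that trims heparan sulfate, had the largest rise on the arrays labelled HT-MT and was at least 9.15-fold higher than in HT (adjusted p = 1.07e-08). MMP9, the secreted gelatinase B, had the largest fitted fall and was at least 9.34-fold lower (adjusted p = 7.87e-09), falling from a mean signal of 4539 ± 425 (SD, n = 2) to below detection. The laminin chain LAMA5 fell 6.78-fold (log2 -2.76 ± 0.09, adjusted p = 2.83e-08). The others of the 10 largest fitted rises were in MAGEE1 (at least 3.02-fold), ARHGAP4 (at least 3.85-fold) and the monocyte attractant CCL2 (at least 2.87-fold). They also included GPRC5C (at least 2.22-fold), neuromedin B (NMB, at least 2.35-fold), F8A1 (at least 3.37-fold), the mesenchymal cadherin CDH11 (at least 2.73-fold), the cation exchanger SLC24A3 (at least 1.91-fold) and the class II chain HLA-DPA1 (at least 5.29-fold). The others of the 10 largest fitted falls included the cancer-testis antigen MAGEA1 (at least 3.04-fold), the membrane peptidase neprilysin (MME, 4.50-fold), and HECW2 (at least 1.86-fold). The actin-bundling protein LCP1 fell 4.16-fold and the stress-response factor DDIT3 3.79-fold. VCX (at least 1.54-fold), neuroserpin (SERPINI1, at least 1.84-fold) and VCX2 (at least 1.12-fold) fell below detection. The adjusted p of CDH11 was 1.14e-06, and those of the other genes named here lay between 7.87e-09 and 2.01e-07.

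Of all 6336 genes tested, 39.2% passed the threshold in HT-MT against HT, higher and lower together, so members of most lists would pass as well. Of 29 extracellular matrix genes, 19 rose and 5 fell in HT-MT (19 and 5 adjusted over the list alone). Thrombospondin 1 (THBS1), an adhesive matrix glycoprotein, rose 7.61-fold (log2 2.93 ± 0.09, adjusted p = 2.08e-08), the proteoglycan versican (VCAN) 6.92-fold and the basement membrane protein NID2 at least 1.20-fold, beside the fall of LAMA5. The list was higher by camera (adjusted p = 3.67e-04; adjusted p = 0.3714 with an estimated correlation). Of 33 genes of the hypoxia response and glycolysis, 18 rose and 3 fell (19 and 3 adjusted over the list alone), among them the glucose transporter SLC2A1 (at least 1.43-fold), the glycolytic enzyme PGAM1 (1.68-fold), the collagen prolyl hydroxylase P4HA1 (1.64-fold) and PGM1 (1.59-fold). Camera called it higher (adjusted p = 0.0016; 0.4391 as the adjusted p with an estimated correlation). Interferon-stimulated genes numbered 22, of which 11 rose and 1 fell (12 and 2 adjusted over the list alone). IFI27 was at least 3.89-fold higher, IFITM1 2.32-fold, IFI6 2.27-fold and the antiviral GTPase MX1 at least 1.67-fold. This list too was higher by camera (adjusted p = 0.0022; adjusted p = 0.3714 with an estimated correlation). In cholesterol synthesis 7 of 15 genes rose and 2 fell (7 and 2 adjusted over the list alone), among them INSIG1 (2.17-fold). That call (adjusted p = 0.0288) was lost with an estimated correlation (adjusted p = 0.4007) and with the detection threshold of 0.05 (adjusted p = 0.0599).

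Other lists were not called in HT-MT against HT, though members of each passed the threshold, as did 39.2% of all genes tested. Of 20 other pericellular proteases and inhibitors, 8 rose and 4 fell (9 and 5 adjusted over the list alone), with the metalloproteinase inhibitor TIMP3 4.33-fold and tissue plasminogen activator (PLAT) 3.76-fold higher and the serpin SERPINE2 1.68-fold lower. Only 3 other matrix metalloproteinases could be tested: MMP2 rose 1.91-fold (adjusted p = 8.55e-04), MMP9 fell and MMP17 did not pass. In TGF-beta and BMP signalling 10 of 19 genes rose and 4 fell (10 and 4 adjusted over the list alone), led by the activin subunit INHBA (4.21-fold), SMAD3 (2.79-fold) and LTBP3 (2.36-fold). Its camera call did not pass (adjusted p = 0.0627) but did without HT replicate 1 (adjusted p = 0.0389) or without HT-MT replicate 1 (adjusted p = 0.0475; 0.0106 to 0.2344 over the 21 settings). Of 12 inflammatory cytokines and NF-kB targets 6 rose and 3 fell (6 and 4 adjusted over the list alone), IL1B, the cytokine interleukin 1 beta, by 7.42-fold and IL11 by 1.60-fold. Camera gave it an adjusted p of 0.0842, or 0.0389 without HT replicate 1 (5.32e-05 to 0.8381 over the 21 settings). Oxidative phosphorylation had 8 higher and 2 lower of 41 (4 and 2 adjusted over the list alone; adjusted p = 0.0627, and 0.0389 without HT replicate 1 or 0.0370 without HT-MT replicate 2; 0.0174 to 0.4868 over the 21 settings). Heat shock and chaperones had 8 higher and 1 lower of 13 (8 and 1 adjusted over the list alone; adjusted p = 0.0800), with HSPA8 1.62-fold higher. It was called among probes detected on all 6 arrays (adjusted p = 0.0473) and from the second table after median centring (adjusted p = 0.0451; up to 0.2202 over the 21 settings). In the unfolded protein response and amino acid stress, 8 of 27 genes rose and 12 fell (9 and 12 adjusted over the list alone), and DDIT3, TRIB3 (3.52-fold), SESN2 (log2 -1.59) and XBP1 (1.83-fold) were lower. From the second table that list was called lower (adjusted p = 0.0243; up to 0.3870 over the 21 settings). Integrins and focal adhesion had 5 of 25 higher and 7 lower (5 and 7 adjusted over the list alone), with the collagen receptor subunit ITGA11 at least 2.45-fold and the fibronectin receptor subunit ITGA5 1.99-fold higher. Camera's adjusted p was at least 0.2471 for the last 2 lists and for the proteases.

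Camera called none of the remaining lists in HT-MT, with an adjusted p of 0.2471 or above, which does not show that they did not change. Angiogenic factors had 2 of 10 higher and 6 lower (2 and 6 adjusted over the list alone): ANGPTL2 was at least 1.81-fold higher, and VEGFC (1.60-fold), PDGFC (1.55-fold) and HBEGF (1.49-fold) fell. Their median log2 difference was -0.40, and among probes detected on all 6 arrays the list was called lower (adjusted p = 0.0193; up to 0.4577 over the 21 settings). Cell cycle and mitosis had 5 of 37 higher and 10 lower (5 and 10 adjusted over the list alone), with the licensing factor CDT1 1.85-fold lower. Of 11 Wnt and Dickkopf genes 3 rose and 3 fell (4 and 4 adjusted over the list alone), WNT5A by 2.95-fold and SFRP1 by at least 2.64-fold upward. Endocytosis and membrane trafficking had 9 of 29 higher and 1 lower (8 and 1 adjusted over the list alone), p53 targets 5 of 14 and 6 (6 and 6 adjusted over the list alone), and ribosomal proteins 2 of 46 and 2 (0 and 0 adjusted over the list alone). Ribosomal proteins were called lower from the second table (adjusted p = 0.0495) and after its median centring (adjusted p = 0.0047; up to 0.5651 over the 21 settings). Notch signalling had 1 of 5 higher and 2 lower (1 and 2 adjusted over the list alone), with the Notch target HEY1 at least 1.74-fold lower. Mesenchymal markers had 2 of 8 higher and 3 lower (3 and 3 adjusted over the list alone), with the receptor PDGFRB at least 1.57-fold higher and the receptor kinase AXL 1.61-fold lower.

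The comparison of HT-siRNA with HT was designed to ask what loss of MT1-MMP changes. It also sets stably transfected cells against parental ones. Without a scrambled control among these arrays, it cannot separate silencing from transfection and selection. Of the genes named below, IL1B, PLAT, SFRP1, F8A1, MMP9, LAMA5, MAGEA1 and SERPINI1 moved in the same direction in HT-MT, where MMP14 was still detected. By fitted values IL1B rose most in HT-siRNA cells, 24.4-fold above HT (log2 4.61 ± 0.08, adjusted p = 7.54e-10), from a mean signal of 913.7 ± 62.9 to 22231 ± 381 (SD, n = 2 each). MMP14 and MMP9 were the genes with the largest fitted falls, and MMP9 was at least 9.50-fold lower (adjusted p = 7.54e-10). LAMA5 fell 9.09-fold (log2 -3.18 ± 0.09, adjusted p = 9.99e-09). PLAT rose 9.02-fold, the adhesion molecule CADM1 10.5-fold and SFRP1, a secreted Wnt antagonist, at least 7.81-fold. Calretinin (CALB2) was at least 9.56-fold higher, F8A1 at least 7.55-fold, and podoplanin (PDPN) at least 4.76-fold. So were the retinaldehyde dehydrogenase ALDH1A3 (at least 3.20-fold), ARHGEF4 (at least 2.49-fold) and thrombomodulin (THBD, at least 1.85-fold). Further falls were in ARHGDIB (at least 5.42-fold), LOC81569 (at least 4.82-fold), dermokine (DMKN, at least 4.72-fold) and SERINC2 (at least 3.91-fold). The inhibin subunit INHBE (at least 3.58-fold), MAGEA1 (at least 3.09-fold) and SERPINI1 (at least 1.87-fold) fell too. Adjusted p-values of these genes lay between 7.54e-10 and 5.64e-07.

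In HT-siRNA against HT 50.4% of all genes tested passed the threshold, higher and lower together, which is the share to set beside the list counts. Cell cycle and mitosis genes were higher in HT-siRNA: 20 of 37 rose and 2 fell (20 and 3 adjusted over the list alone), among them cyclin D3 (CCND3, 1.96-fold), the ubiquitin-conjugating enzyme of mitosis UBE2C (1.71-fold), the mitotic kinesin KIF20A (1.66-fold) and cyclin B1 (CCNB1, 1.56-fold). Camera called the list (adjusted p = 0.0209), but not with an estimated correlation (adjusted p = 0.3845) or among probes detected on all 6 arrays (adjusted p = 0.0521). Heat shock genes and chaperones had 8 of 13 higher and 1 lower (9 and 1 adjusted over the list alone), with HSPA8 2.38-fold, HSPA1B 2.19-fold, HSPA1A at least 1.28-fold and HSPH1 1.57-fold higher (adjusted p = 0.0219; adjusted p = 0.4770 with an estimated correlation). Endocytosis and membrane trafficking had 12 of 29 higher and 2 lower (12 and 2 adjusted over the list alone): CHMP4B rose 1.65-fold, VAMP3 1.58-fold and RAB22A 1.44-fold, and SNX2 fell 1.78-fold. Its call (adjusted p = 0.0325) was lost with an estimated correlation (adjusted p = 0.4841) and under 5 other settings, among them leaving out HT replicate 1 (adjusted p = 0.1179) or HT-siRNA replicate 2 (adjusted p = 0.0792). Cytosolic ribosomal proteins, a measure of RNA quality and array scale as much as of translation, had 13 of 46 lower and 0 higher (3 and 0 adjusted over the list alone; adjusted p = 0.0219, or 0.3845 as the adjusted p with an estimated correlation), and RPL22 fell 1.35-fold, RPS28 1.27-fold, RPS15 1.26-fold and RPS2 1.25-fold. Of these genes RPS28 lost its call without HT-siRNA replicate 1 (adjusted p = 0.0685; from 5.27e-04 over the 21 settings) and RPS15 without HT-siRNA replicate 2 (adjusted p = 0.0639; from 0.0052). RPS2 lost it without HT replicate 2 (adjusted p = 0.1406), without HT-siRNA replicate 1 (log2 -0.19 against -0.33, adjusted p = 0.2395) and with no filter on dim probes (adjusted p = 0.0648; 4.67e-05 to 0.2395 over the 21 settings).

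In HT-siRNA the matrix and interferon lists tended lower without a camera call. Of 29 extracellular matrix genes 14 fell and 8 rose (15 and 9 adjusted over the list alone; adjusted p = 0.3855), with the collagen crosslinking enzyme LOX at least 2.67-fold and the basement membrane collagen COL4A1 3.15-fold lower and VCAN 3.06-fold higher. Of 22 interferon-stimulated genes 11 fell and 5 rose (11 and 6 adjusted over the list alone; adjusted p = 0.3387): ISG20 fell 3.74-fold, HLA-B 2.16-fold and the transcription factor IRF1 2.05-fold, and IFI27 was at least 2.13-fold higher. In the unfolded protein response and amino acid stress DDIT3 fell 4.84-fold, TRIB3 4.60-fold, the serine synthesis enzyme PHGDH 3.62-fold and the folate enzyme MTHFD2 3.24-fold, within a list of 27 of which 13 fell and 8 rose (13 and 9 adjusted over the list alone). Camera gave that list an adjusted p of 0.0761, and 0.0363 without HT-siRNA replicate 1 (2.23e-04 to 0.1097 over the 21 settings). Of 14 p53 targets 6 fell and 4 rose (6 and 4 adjusted over the list alone; adjusted p = 0.2214), with GADD45A 3.23-fold, SESN2 2.52-fold and PMAIP1 2.19-fold lower. Of 12 inflammatory cytokines and NF-kB targets 7 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.1875), among them the prostaglandin synthase PTGS2 (at least 1.37-fold), LIF (1.83-fold) and IL11 (1.80-fold). That list was called higher from the second table (adjusted p = 6.85e-04; up to 0.7733 over the 21 settings).

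No camera call was made in HT-siRNA for the other lists, whose adjusted p was 0.1875 or above. Of 20 pericellular proteases and inhibitors 6 rose and 6 fell (8 and 6 adjusted over the list alone), with SERPINE2 1.92-fold and the disintegrin protease ADAM15 1.85-fold lower, and of the 3 matrix metalloproteinases tested only MMP9 passed. Integrins and focal adhesion had 7 of 25 higher and 11 lower (7 and 11 adjusted over the list alone), with syndecan 4 (SDC4) 2.25-fold higher and talin 2 (TLN2) at least 2.14-fold lower. In TGF-beta and BMP signalling 6 of 19 rose and 9 fell (6 and 9 adjusted over the list alone), with LTBP3 3.56-fold and SMAD3 2.56-fold higher and the BMP target ID3 2.24-fold lower. Hypoxia and glycolysis had 15 of 33 higher and 8 lower (15 and 8 adjusted over the list alone), with DDIT4 2.41-fold lower and BHLHE40 1.89-fold higher. Wnt and Dickkopf signalling had 4 of 11 higher and 5 lower (4 and 5 adjusted over the list alone), WNT5A rising 2.76-fold and DKK3 falling 2.02-fold, and cholesterol synthesis 6 of 15 and 2 (6 and 2 adjusted over the list alone), INSIG1 rising 2.14-fold. Angiogenic factors had 1 of 10 higher and 4 lower (1 and 4 adjusted over the list alone), SEMA3F falling 2.94-fold, and Notch signalling 0 of 5 and 3 (0 and 3 adjusted over the list alone). The angiogenic list was not sorted by effect on vessel growth, so a lower member such as SEMA3F does not mean less of it. Oxidative phosphorylation had 9 of 41 higher and 1 lower (5 and 0 adjusted over the list alone) and mesenchymal markers 3 of 8 and 4 (3 and 4 adjusted over the list alone).

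The direct comparison sets the means of the transfected pools against each other, and it rests on the label HT-MT. The HT arrays enter its p-values through the common estimate of spread. PCOLCE, which enhances procollagen processing, was at least 6.46-fold higher on the arrays labelled HT-MT than in HT-siRNA (adjusted p = 4.24e-09), SULF2 at least 8.86-fold and LRRC17 7.54-fold (log2 2.91 ± 0.10). Also among the largest differences were MAGEE1 (at least 2.92-fold), ARHGAP4 (at least 3.73-fold), the potassium-chloride cotransporter SLC12A7 (at least 1.94-fold), the mucin MUC6 (at least 2.19-fold), FEZ1 (at least 1.40-fold) and MAGED4 (at least 1.49-fold). Lower on the arrays labelled HT-MT were PTPRN (at least 5.37-fold), ALDH1A3 (at least 3.05-fold), the prostaglandin E synthase PTGES (at least 2.72-fold), DKFZP434B061 (at least 2.67-fold), PDPN (3.82-fold) and THBD (at least 1.76-fold). The collagen COL22A1 (at least 1.57-fold), VCX (at least 1.36-fold), the sterol transporter ABCG1 (at least 1.23-fold) and the trypsin inhibitor SPINK1 (at least 1.20-fold) were lower too. The adjusted p of these genes was at most 9.17e-07.

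Between the pools 34.5% of all genes tested passed the threshold, higher and lower together. Of 29 extracellular matrix genes, 19 were higher and 3 lower on the arrays labelled HT-MT than in HT-siRNA (20 and 3 adjusted over the list alone). COL4A1 differed 6.33-fold, THBS1 3.47-fold, the fibrillar collagen COL5A1 3.45-fold and the laminin chain LAMA4 at least 1.69-fold. All 14 interferon-stimulated genes that passed, of 22, were higher (14 and 0 adjusted over the list alone), with IFITM1 3.39-fold, ISG20 3.25-fold, HLA-B 2.76-fold and MX1 at least 1.62-fold. Cell cycle and mitosis genes were lower, 21 of 37 against 2 higher (22 and 2 adjusted over the list alone), and UBE2C differed 2.20-fold, the replication helicase subunit MCM5 1.67-fold, TPX2 1.60-fold and the mitotic kinase AURKB 1.57-fold. Camera's adjusted p was 4.12e-08, 1.30e-05 and 3.17e-05 for these lists, and the adjusted p with an estimated correlation was 0.1015 for each. The unfolded protein response and amino acid stress list had 13 of 27 higher and 3 lower (14 and 3 adjusted over the list alone), with PHGDH 2.16-fold, MTHFD2 1.93-fold, HERPUD1 1.86-fold and the chaperone HSPA5 1.65-fold (adjusted p = 0.0146; adjusted p = 0.2214 with an estimated correlation). The calls of hypoxia and glycolysis (10 of 33 higher and 4 lower; 11 and 4 adjusted over the list alone; adjusted p = 0.0475), with CA12 2.79-fold and HIF1A 2.37-fold higher, and of ribosomal proteins (3 of 46 higher and 1 lower; 0 and 0 adjusted over the list alone; adjusted p = 0.0443) had an adjusted p of 0.6138 and 0.2214 with an estimated correlation. The first was lost with only the 4 arrays compared (adjusted p = 0.0540). Leaving out either HT array gives that same fit, so it does not show dependence on an HT array. The first was also lost without HT-MT replicate 2 (median log2 difference 0.1026) or HT-siRNA replicate 1 (0.0636). The second was lost without HT-MT replicate 1 (adjusted p = 0.0871), HT-MT replicate 2 (adjusted p = 0.0528) or HT-siRNA replicate 1 (adjusted p = 0.1216). Both were also lost with the replicate number as a block (adjusted p = 0.0512 for each) and with quantile normalization (adjusted p = 0.0625 and 0.1401). Of the 21 settings 9 ended the first call and 7 the second. The 9 count the 4-array fit and both of its repeats separately. TIMP3 was 5.60-fold higher, the activin antagonist FST at least 2.29-fold higher and IL1B 3.28-fold lower on the arrays labelled HT-MT.

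Between the transfected pools, TGF-beta and BMP signalling missed the threshold (7 of 19 higher and 2 lower; 7 and 3 adjusted over the list alone; adjusted p = 0.0531) and passed it without HT-MT replicate 1 (adjusted p = 0.0480) or without HT-siRNA replicate 2 (adjusted p = 0.0354; 0.0018 to 0.1773 over the 21 settings). Heat shock and chaperones had 0 of 13 higher and 5 lower (1 and 5 adjusted over the list alone; adjusted p = 0.0954, or 0.0475 without HT-siRNA replicate 2; 0.0419 to 0.1925 over the 21 settings). The other lists had a camera adjusted p of at least 0.1893. All 3 matrix metalloproteinases tested besides MMP14 passed the threshold upward, MMP2 by 1.56-fold, MMP17 by 1.23-fold and MMP9 with no fold, being below detection in both pools. MMP2 lost its call without HT-MT replicate 1 (adjusted p = 0.0774) or HT-siRNA replicate 1 (adjusted p = 0.0529; 7.19e-08 to 0.0774 over the 21 settings). MMP17 lost it without each of HT-MT replicates 1 and 2 and HT-siRNA replicates 1 and 2 (adjusted p = 0.0579 to 0.1291), with no filter on dim probes and from the second table after median centring (adjusted p = 0.0595 and 0.1346; 0.0087 to 0.1346 over the 21 settings). Proteases and inhibitors had 5 of 20 higher and 4 lower (5 and 4 adjusted over the list alone), with PLAT 2.40-fold and cathepsin L (CTSL) 1.79-fold lower. Integrins and focal adhesion had 8 of 25 and 3 (8 and 3 adjusted over the list alone), Wnt and Dickkopf 3 of 11 and 4 (3 and 4 adjusted over the list alone) and angiogenic factors 2 of 10 and 3 (2 and 6 adjusted over the list alone). In p53 targets 5 of 14 were higher and 1 lower (5 and 2 adjusted over the list alone), led by GADD45A (2.00-fold), in cytokines and NF-kB targets 2 of 12 and 3 (3 and 3 adjusted over the list alone), and in cholesterol synthesis 4 of 15 and 0 (4 and 0 adjusted over the list alone). Endocytosis had 2 of 29 and 6 (1 and 6 adjusted over the list alone), Notch signalling 2 of 5 and 2 (2 and 2 adjusted over the list alone), mesenchymal markers 3 of 8 and 1 (3 and 2 adjusted over the list alone) and oxidative phosphorylation 3 of 41 and 3 (0 and 0 adjusted over the list alone).

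**Figure D2:**
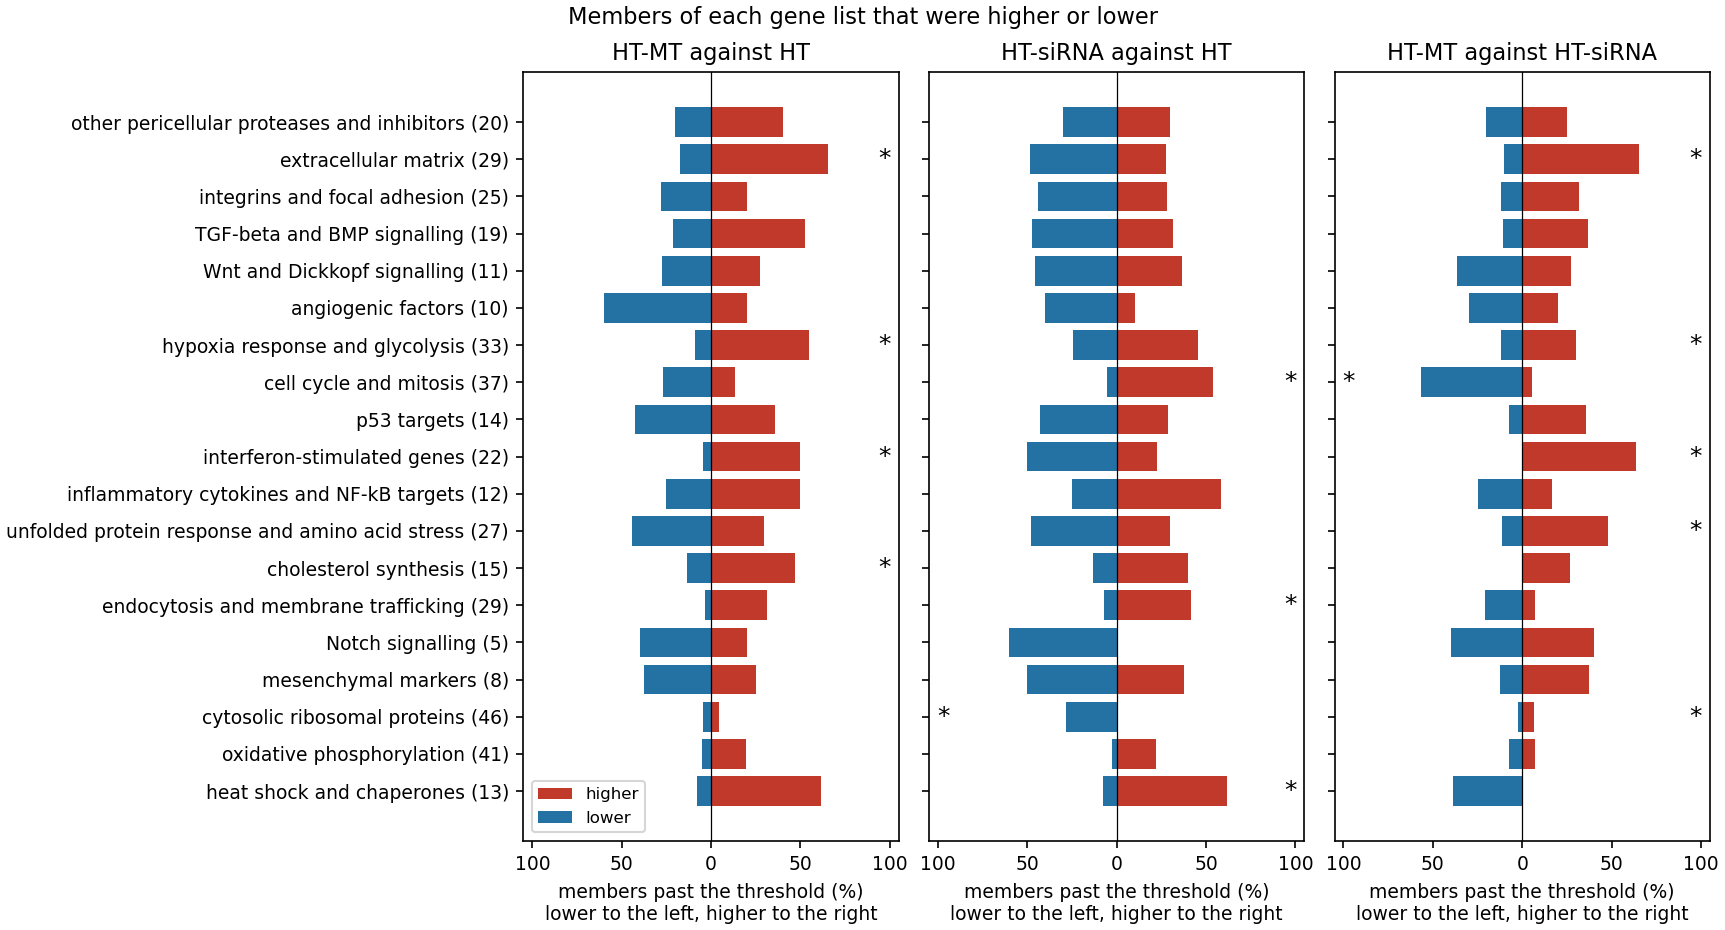
Percent of the tested members of each of 19 gene lists (number tested in brackets) that were higher (right) or lower (left) past the adjusted threshold of 0.05 in the 3 comparisons; a star marks a camera call at the preset correlation, and no call held with an estimated correlation. Extracellular matrix genes were mostly higher in HT-MT against HT (19 of 29) and against HT-siRNA (19 of 29), while 14 of 29 were lower in HT-siRNA against HT. Of all genes tested, 39.2% passed in HT-MT against HT, 50.4% in HT-siRNA against HT and 34.5% in HT-MT against HT-siRNA.

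In number, 2486 genes differed between HT-MT and HT (1150 higher, 1336 lower), 3193 between HT-siRNA and HT (1596 higher, 1597 lower) and 2188 between HT-MT and HT-siRNA (1043 higher, 1145 lower). Most differences were small: by fitted values, 207, 313 and 206 of these genes differed by 2-fold or more. In the first comparison 142 of the 207 were higher, in the second 188 of the 313 were lower, and in the third 158 of the 206 were higher. Without HT-MT replicate 1 the first count was 1397 and the third 1271, without HT-MT replicate 2 they were 1556 and 1339, and without HT-siRNA replicate 2 the third was 1445. Limma assumes then that the array left alone in its group varies like the other groups.

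If changes followed the designed amount of MT1-MMP, genes would move in opposite directions in the transfected pools. The measured MMP14 signal was not higher in HT-MT than in HT (log2 -0.30) and was below detection in HT-siRNA. By that signal no opposite movement would be expected, so the counts do not test dependence on the measured amount. Of 1799 genes past the threshold against HT in both pools, 183 moved in opposite directions, 102 of them higher in HT-MT and lower in HT-siRNA and 81 the reverse. By fitted values the largest were PCOLCE (4.08-fold higher and at least 1.59-fold lower), LRRC17 (2.28-fold higher, 3.30-fold lower), PXDN, a peroxidase of the matrix (1.46-fold higher, 4.44-fold lower), COL4A1 (2.01-fold higher, 3.15-fold lower) and the hedgehog-binding protein HHIP (1.93-fold higher, at least 2.05-fold lower). PTPRN went the other way (at least 1.09-fold lower, 4.93-fold higher). SLC12A7 (at least 2.00-fold), FEZ1 (at least 1.45-fold) and ANGPTL2 (at least 1.81-fold) were higher in HT-MT, with no fold in HT-siRNA, and COL22A1 was at least 1.65-fold higher in HT-siRNA with no fold in HT-MT. The opposite direction of FEZ1 and of COL22A1 was not stable. The HT-siRNA call of FEZ1 (log2 -0.25, both groups below detection) was lost under 10 of 20 settings. Among them were leaving out HT replicate 1 (-0.16) or either HT-siRNA array. The 10 also count the fit of only the 4 arrays compared and its repeats, the fits without either HT-MT array. The HT-MT call of COL22A1 (-0.39, both groups below detection) was lost under 5, among them leaving out HT replicate 1 (-0.17) or either HT-MT array, and was -0.61 without HT replicate 2. These directions rest on the label HT-MT. The count of opposite genes was 89 without HT-MT replicate 1, 100 without HT-MT replicate 2, 98 among probes detected on all 6 arrays, 107 from the second table and 102 from that table after median centring.

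Far more genes moved in the same direction: 1616 of the 1799 (89.8%), 743 higher and 873 lower in both pools. IL1B, PLAT, VCAN, IFI27 and INSIG1 rose in both, and MMP9, LAMA5, MAGEA1, SERPINI1, DDIT3, TRIB3 and SESN2 fell in both. Independent lists of the same sizes would share 289.7 higher and 336.7 lower genes, and 626.4 in opposite directions. Across genes, which are not independent replicates, the log2 differences of both pools from HT correlated at r = 0.6104, against a highest value of 0.5275 in 100 simulations of unchanged groups sharing their controls. Their covariance was 0.1393, against a simulated mean of 0.0046 and a highest value of 0.0051. The difference between the covariances estimates what both pools share against these HT arrays beyond the spread between replicates. The simulations held only that spread, so a deviation of the HT cultures themselves would count in full. Part of the excess in the overlap and in r may come from the shared HT arrays. The sign was the same in 74.0% of all genes, against a mean of 66.7% in the simulations, in which at most 1 gene was past the threshold in both. No gene was changed in those simulations, so hardly any could pass in either comparison. That count is therefore no reference for the 1799 genes found. Without HT-MT replicate 1 the count of genes moved in the same direction was 962, and without HT-MT replicate 2 it was 1039.

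**Figure D3:**
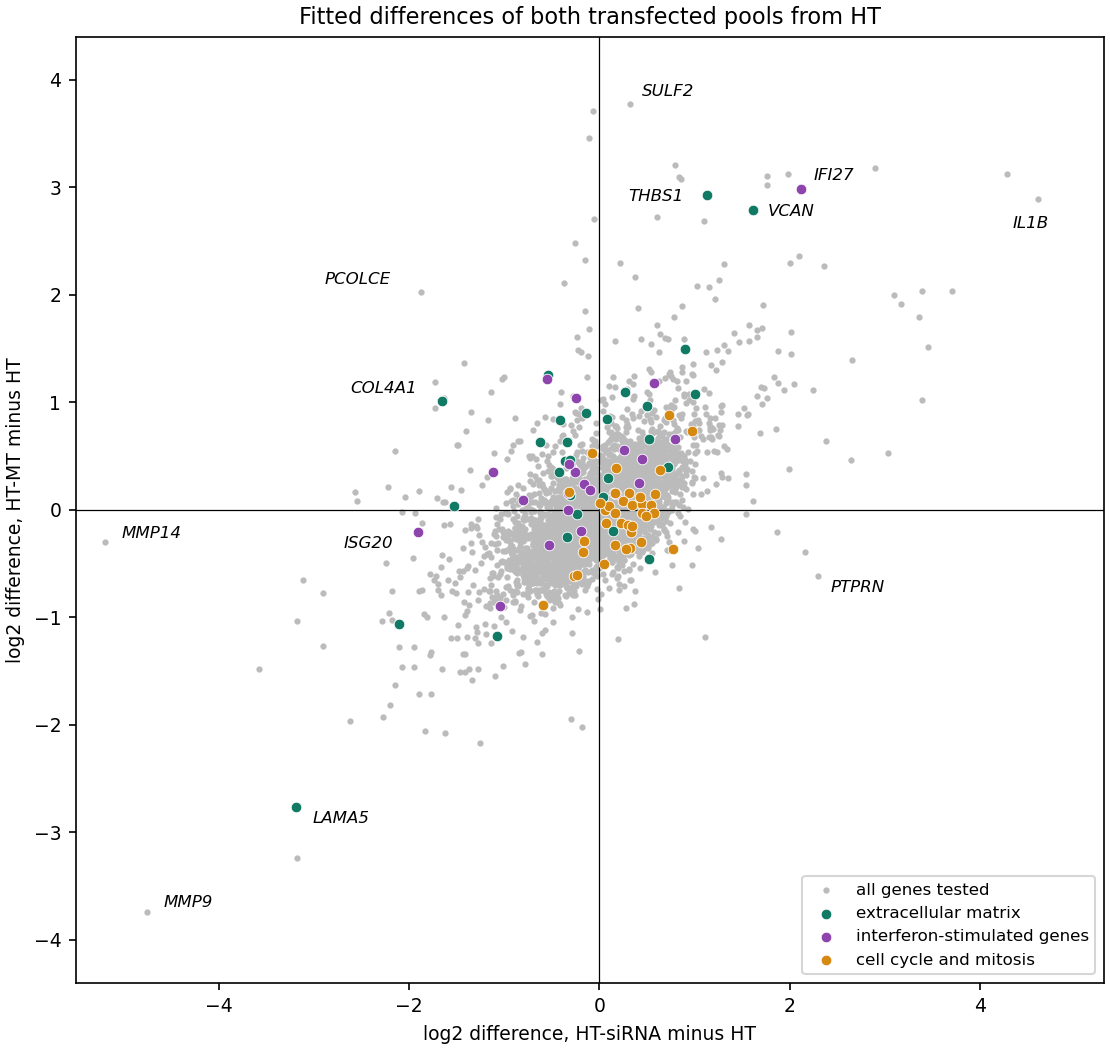
Fitted log2 difference of each of 6336 genes from HT in HT-siRNA (horizontal axis) and in HT-MT (vertical axis), with extracellular matrix, interferon-stimulated and cell cycle genes coloured; genes below detection in a group are drawn at fitted values. Most genes lie in the quadrants of equal sign (74.0%), MMP9 and LAMA5 are low in both, MMP14 is low in HT-siRNA only, and COL4A1 and PCOLCE are higher in HT-MT and lower in HT-siRNA.

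Of the 2188 genes that differed between HT-MT and HT-siRNA, 981 had an HT mean between those of the pools, as an order by designed MT1-MMP level would give, 431 highest and 550 lowest in HT-MT, and 1207 had it outside. Without HT-MT replicate 1 the first count was 625. No share to expect without an order by designed level was computed, and picking genes by a gap between the pools itself favours an HT mean between them. The count therefore does not test such an order. MMP14 itself had its HT mean outside (7562 in HT, 6075 in HT-MT and 205 in HT-siRNA). The ordered genes with the largest fitted changes were PCOLCE, LRRC17, PTPRN, SLC12A7, FEZ1 and PXDN, which were also opposite in both tests against HT (FEZ1 not stably), and MAGEE1, ARHGAP4, MUC6 and MAGED4. MAGEE1, ARHGAP4 and MUC6 were below detection in both HT and HT-siRNA, and MAGED4 differed between HT-MT and HT by 0.16 ± 0.10 on the log2 scale (adjusted p = 0.2017), so their order rests on a single step.

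Markers of other cell types were few above detection. Of 4 epithelial markers tested, KRT8 (2.44-fold) and KRT18 (1.58-fold) were higher in HT-MT than in HT (2 and 1 lower adjusted over the list alone), and KRT8 (1.67-fold), KRT7 (at least 1.19-fold) and GATA3 (1.39-fold) were higher in HT-siRNA (3 and 0 lower adjusted over the list alone). The glial marker CNP was 1.45-fold and 1.56-fold higher. The leukocyte marker CD74, the class II invariant chain, was at least 1.86-fold higher in HT-MT (adjusted p = 6.50e-07), beside the rise of HLA-DPA1 and of the interferon-stimulated genes. In HT-siRNA CD74 also passed upward (log2 0.37, adjusted p = 0.0226), with no fold, being below detection there and in HT. That call was lost without HT replicate 1 (adjusted p = 0.0900) or HT-siRNA replicate 2 (adjusted p = 0.1762; 0.0076 to 0.1762 over 20 settings). CSF1R was 1.28-fold lower in HT-siRNA. The endothelial receptor TIE1 fell 2.75-fold in HT-MT and at least 3.45-fold in HT-siRNA. Between the pools, epithelial markers had 2 higher and 2 lower, glial markers 0 and 1, leukocyte markers 2 and 0, with CD74 at least 1.80-fold and CSF1R 1.51-fold higher, and endothelial markers 1 and 0. The calls of KRT8, GATA3 and SOX9 between the pools were each lost under at least 1 setting.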

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

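The test of an interferon response to double-stranded RNA and that of normalization, in the form given here, were chosen only after the results were seen, and the test of other cell types was chosen before. Differences between the effects of both pools against HT were tested in the contrast of HT-MT with HT-siRNA, which is the difference between those effects and rests on the label HT-MT. By camera the extracellular matrix list differed at an adjusted p of 4.12e-08, cell cycle and mitosis at 3.17e-05 and interferon-stimulated genes at 1.30e-05. With an estimated correlation each had an adjusted p of 0.1015, so none of them passed then. A p that misses the threshold does not show that there is no difference. For cell cycle genes no explanation was tested.

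Matrix and interferon-stimulated genes lay above HT in HT-MT and tended below it in HT-siRNA. Leukocytes or endothelial cells could bring such transcripts into the HT-MT cultures as a hypothesis, but of the markers of either cell type at most 6.25% were gained there. That was CD74 alone, of 16 leukocyte markers, with mean signals of 192.1 in HT and 864.6 in HT-MT. HT itself showed 1 of the 16 leukocyte and 2 of the 12 endothelial markers. The class II gene HLA-DPA1, which is outside these lists, rose in HT-MT too. The lowest detected signals of the HT-MT arrays were 498.4 and 471.9. Markers of a small admixture could stay below that, so this test cannot exclude one. The authors' normalization could also have set these lists apart. From the second table as deposited, whose array medians were not equal, the higher adjusted p of both lists was 2.03e-06, which argues against a normalization that only the first table has. The size of that p is not comparable with those of the main values. Camera compares a list with other genes, so this test bears on changes beyond a factor per array. What the authors did to the second table is not stated, so a step common to both tables stays open.

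A response to double-stranded RNA from the siRNA construct, which would raise interferon-stimulated genes in HT-siRNA, cannot be told apart from no such response. By fry the list moved down there (adjusted p = 0.0019), but that restates the pattern, 5 of its genes rose while 11 fell, and camera did not call it (adjusted p = 0.3387). The test was first read as evidence against this response. The condition that no gene pass the other way was added later, and under it the test gives no decision. An effect of MT1-MMP itself and a difference between pools that arose at transfection or selection also remain, and these arrays hold no test that separates them.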

How the results depend on the processing

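The camera calls depended on the form of the test. With an estimated correlation 0 lists were called in HT-MT against HT, 0 in HT-siRNA against HT and 0 in HT-MT against HT-siRNA, and with fry 16, 14 and 11. Among the lists called, the estimated correlation was above 0.01 for extracellular matrix (0.0297), hypoxia and glycolysis (0.1696), endocytosis (0.1232) and heat shock (0.0492). It was below 0.01 for interferon-stimulated genes (-0.0432), cholesterol synthesis (-0.0573), cell cycle (-0.0031), ribosomal proteins (-0.0093) and the unfolded protein response (0.0077). For these last lists a larger correlation cannot be what ended the calls. For interferon-stimulated genes in HT-MT against HT-siRNA, camera with an estimated correlation gave an unadjusted p of 0.0129, against an adjusted 1.30e-05 at the preset. Losing every call in this form therefore does not by itself show correlation between genes. Among probes detected on all 6 arrays 7 lists were called in HT-MT against HT and 98 genes moved in opposite directions, and MMP14 had no value. The second table gave 8 lists and 107 opposite genes, and after median centring 8 lists, 102 opposite genes and an MMP14 difference of -0.46. That centring also moved the median difference of all genes in HT-MT against HT to -0.12. With the replicate number as a block the MMP14 difference stayed at -0.30 but passed the threshold (adjusted p = 0.0413). That block also ended the calls of hypoxia and glycolysis and of ribosomal proteins in HT-MT against HT-siRNA (adjusted p = 0.0512 for each). Whether the numbers pair the cultures is open, since deviations of arrays of the same number correlated at -0.19 between HT and HT-MT, 0.53 between HT and HT-siRNA and -0.10 between HT-MT and HT-siRNA. With a block and only the HT and HT-MT arrays 2252 genes differed with the numbers as given and 2695 with those of HT-MT crossed, against 2348 without a block. All arrays shared a chip, so chip was not run as a block. Replicates 1 filled the first positions used and replicates 2 the last, so the replicate block is also a block on that part of the chip, and no other position block was run.

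Leaving out each array in turn gave 1397 to 2585 genes differing in HT-MT against HT, 2363 to 3226 in HT-siRNA against HT and 1271 to 2543 in HT-MT against HT-siRNA. Lists called ranged from 4 to 7, 3 to 5 and 4 to 8. Opposite genes ranged from 89 to 153, same-direction genes from 962 to 1735 and ordered genes from 625 to 1078. The fitted MMP14 difference between HT-MT and HT ranged from -0.51 to -0.0914, that between HT-siRNA and HT from -5.40 to -4.98 and that between HT-MT and HT-siRNA from 4.78 to 5.002. The last 2 are fitted values against HT-siRNA arrays below detection and no bounds. In these runs the array left alone in a group was assumed to vary like the other groups. Of 333 named gene calls 46 were lost under at least 1 of 21 settings, 43 of them on leaving out an array, and the largest difference among those lost was 0.68 on the log2 scale. No named gene or list turned direction with a call on both sides. For the results that changed, the cause was not tested.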

Other observations

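The tests of exchanged arrays, of exchanged labels and of the second bound on saturation were chosen only after MMP14 was seen not to be higher in HT-MT, and the test of normalization took its form here after its values were seen. The other tests of the shared movement of both pools were chosen before it was seen. MMP14 was expected above HT on the arrays labelled HT-MT, and its difference was toward a lower signal. An exchange of an HT array with an HT-MT array could hide a rise, but the lower of the within-group correlations was 0.9927, above the highest of 0.9821 between HT and HT-MT arrays. A signal saturated at the level of MMP14 could hide it too, but 97 genes were measured on both HT-MT arrays at over 2 times the HT signal of MMP14. That bears on the scale of the arrays and cannot exclude a limit of the MMP14 probe itself. A first bound on saturation, at least 10 genes risen by 1.5-fold at that level, found 5 genes and gave no decision, and the second was added then. An exchange of all HT with all HT-MT labels cannot be told apart from correct labels, since MMP14 differed by -0.30 with an adjusted p of 0.0977, and a probe that lies outside the transfected sequence might leave the signal where it is.

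Both transfected pools moved away from HT together. Chance values of the shared HT arrays would give a covariance of at most 0.0051 in the simulations, where 0.1393 was found. The simulations held only the spread between replicates, so a deviation of the HT cultures themselves from both pools stays open. An aberrant HT array could do the same, but without either HT array the covariance was at least 0.1416. The authors' normalization could move both pools alike, but from the second table as deposited, whose array medians were not equal, 1227 genes moved in the same direction, against 1616. That argues against a normalization that only the first table has as the whole cause, though the 1227 calls rest on another estimate of spread than the main ones. What was done to the second table is not stated, so a step common to both tables stays open. Transfection and selection, which both pools shared and HT did not, might account for the movement, and without vector or scrambled controls in these 6 arrays this was not tested (covariance 0.1393). Both comparisons share the HT arrays, so the size of their overlap is not independent evidence for either.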
